A study of Mus musculus with 2 samples.

How the data were processed

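The data were single-cell RNA counts of CD45+ cells, CD45 being the surface protein carried by nearly all leukocytes. Per the labels, mouse pancreatic tumours grown in the pancreas from the 6694c2 line were digested with collagenase, strained, sorted by flow cytometry for CD45 and made into Chromium 5' libraries. There was 1 library from vehicle-treated and 1 from LCL161-treated C57BL/6 mice, after 12 days of treatment. How many mice or tumours were pooled into each library is not given in the sources used here.

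The values in the deposited matrices were whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, not normalized. They were unfiltered, with 31053 genes and 737280 barcodes per library, so that cells had to be called here. The submitters' processing notes name Cell Ranger 3.0.0, Seurat 3.1.4 and the mouse build mm10, with no role for each. No deposited cell annotation was used. Gene positions were taken from the GENCODE vM21 annotation of GRCm38 by gene identifier, and all 91 named genes looked up were found and were protein coding.

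Barcodes were kept with at least 500 UMIs, at least 250 genes and under 10% mitochondrial UMIs, in both libraries alike. Scrublet (scanpy 1.11.5), with an expected doublet rate of 0.8% per 1000 cells, marked 7 vehicle and 2 LCL161 barcodes, which were removed. That is so few that it was not relied on. Barcodes with T-cell or B-cell markers and those of another lineage were therefore set apart as mixed-lineage barcodes and kept out of every class. The pairs were T cell with phagocyte, B cell, neutrophil, mature dendritic cell or cDC1, and B cell with phagocyte, neutrophil or mature dendritic cell. Pairs of myeloid lineages, such as phagocyte with neutrophil, were not looked for and stay in their classes. A lineage counted as present with at least 3 of its markers and at least 5 of their UMIs per 10000. These thresholds were set after the data were seen.

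Both libraries were clustered together without integration, on counts scaled to 10000 per cell and log-transformed, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 (leidenalg 0.10.2, python-igraph 0.11.9). Immunoglobulin and T-cell receptor variable segments, mitochondrial, ribosomal and sex-linked genes were left out of the variable genes. Clusters led by lymphoid markers, and cycling clusters with no marker among their leading genes, were clustered again at resolution 2.0.

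Classes were named from marker lists. A list was a candidate with 3 members each detected in 25% of a cluster's cells. The candidate with the highest score won, the score being the scaled mean marker level plus 0.1 for each member among the 10 genes leading the cluster by fold. A cluster stayed unnamed where a list of another class reached 0.9 of that score, where another class had more markers than its own among the 10 leading genes, where it held under 15 cells, or where its cells' median depth, relative to their own library's median, was under 1/3 and none of its markers was among the 10 leading genes (the lowest such depth among the clusters of the first round was 0.392). This naming rule was revised several times after the data were seen: the weight of leading genes, the tie (first 0.95), the resolution of the second clustering (first 1.0), the reference for folds within it, the comparison with other classes' markers and the minimum cluster size all changed. The values with the earlier tie, resolution and no minimum size, and with no weight for leading genes, are among the alternatives. Names ending in "-like" in the report rest on these markers alone. The mononuclear phagocyte-like class joins the macrophage-like and monocyte-like clusters, and the dendritic-cell-like class joins the conventional, mature and plasmacytoid ones.

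For each class, UMIs were summed per library and given as CPM of that sum, the count scaled to a fixed total. Ratios are log2 of LCL161 over vehicle with an exact conditional binomial 95% interval. Class shares are of all kept cells, with exact Clopper-Pearson 95% intervals. All intervals cover counting error only, not differences between mice, tumours or library preparations. Those of ratios and list medians also leave out differences between the cells of a class. With 1 library per group there is no replicate, so that no significance test, p-value or standard error of a treatment effect was computed and no number of changed genes is given. Where a library held 0 UMIs of a gene, the fold is a bound computed from 3 UMIs. The exact 95% limit of such a ratio lies nearer to no change. No gene under 20 UMIs over both libraries in a class got a fold.

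Genes were named by a rule of size. For mononuclear phagocyte-like and T-cell-like cells these were the 12 highest and 12 lowest ratios (pseudocount 5 CPM) among genes with at least 50 CPM in a library and at least 30 UMIs. For dendritic-cell-like and neutrophil-like cells, the other classes with at least 100 cells in each library, they were the 5 highest and 5 lowest. B-cell-like cells, NK-cell-like cells and the T-cell subsets held fewer cells and have no ranked genes. Mitochondrial, ribosomal, antigen receptor, haemoglobin, sex-linked and unnamed gene models, and markers of another class, were left out of the ranking. Of the genes the rule names, 1 is not reported here. The 2 highest and 2 lowest members of each gene list and a fixed set of genes around the drug target were added.

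The 24 gene lists were cIAP and TNF receptor signalling components, NF-kB targets, interferon-gamma response, type I interferon response, MHC class II presentation, MHC class I presentation, phagocytosis and scavenger receptors, complement, alternative activation and tumour macrophage genes, inflammatory cytokines and myeloid activation, chemokines, cytotoxic effector, T-cell cytokines and costimulation, inhibitory receptors and exhaustion, naive and memory T cell, regulatory T cell, cell cycle, glycolysis and hypoxia, cholesterol and lipid handling, dissociation and immediate early stress, red cell RNA, acinar RNA, ductal or tumour RNA, and sex-linked genes. The lists, the markers, the rule for named genes and all alternatives but those the closing section names as chosen later were fixed before the data were examined. A list's value is the median log2 ratio (pseudocount 5 CPM) of its members with at least 20 UMIs, with a 95% range from 1000 Poisson resamplings of the counts. Its percentile is taken among the medians of 10000 random lists of the same size matched on mean CPM in 20 bins, and describes these libraries only. Members beyond 1.5-fold were counted by size. Some lists share genes with each other or with the class markers, as complement and alternative activation do with the macrophage markers.

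Shares of cells with a UMI were compared after thinning each cell to 1000 UMIs, with shallower cells left out, and are given with the unthinned share and the share in another class, which is a background only where that class lacks the gene.

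The ratio intervals and list medians were checked on Poisson counts simulated at the real means and library sizes, with 200 genes changed by known folds. Poisson counts are what the intervals assume, so the coverage shows only that they were computed correctly. It leaves out genes whose UMIs lie in few cells, for which the real spread is wider than these intervals. In mononuclear phagocyte-like cells (10706 genes run) the 95% intervals held the true ratio for 96.1% of unchanged genes and for 97.7%, 98.1%, 96.4% and 97.9% of genes changed by log2 ratios of -2, -1, 1 and 2. In T-cell-like cells (6542 genes run) these were 96.6% and 97.9%, 96.4%, 92.6% and 93.0%. Of 200 lists of unchanged genes, 3.5% in the phagocyte run and 4.5% in the T-cell run fell outside the central 95% of random lists.

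Alternatives to the main settings covered the UMI minimum, an order-of-magnitude rule for calling cells, the mitochondrial limit, doublets, clustering, naming, the denominator of shares, scaling (including TMM from edgeR 4.0.16 in R 4.3.3), thinning, ambient subtraction, pseudocounts and the filter on list members. The ambient profile of a library is the sum of its barcodes with 1 to 50 UMIs. Other tools were Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9.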

Results

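LCL161 is a small molecule that antagonises inhibitor of apoptosis (IAP) proteins, among them cIAP1 and cIAP2, ubiquitin ligases that restrain the kinase NIK and with it the alternative NF-kB pathway. The series asks how this antagonism bears on pancreatic tumours, their T cells and their mononuclear phagocytes. CD45+ cells sorted from orthotopic 6694c2 tumours of mice given vehicle or LCL161 for 12 days were profiled by droplet 5' RNA sequencing, with 1 library per treatment. The vehicle library held 15470870 UMIs and 2180 kept cells, with a median of 3503.5 UMIs and 1461.5 genes per cell. The LCL161 library held 17767074 UMIs and 1946 kept cells, with medians of 5914.5 UMIs and 1983 genes. The genes that encode the drug's targets lie side by side on chromosome 9 (GRCm38), Birc2 (cIAP1, ENSMUSG00000057367) at 7818227 to 7837064 and Birc3 (cIAP2, ENSMUSG00000032000) at 7848699 to 7873186, both on the minus strand. All comparisons below set 1 library against 1 library without a replicate, and their intervals cover counting error only.

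The first comparison asked which leukocytes made up the sorted cells. Lymphocytes made up more of the LCL161 library: T-cell-like cells were 1.24% of vehicle cells (27 cells, interval 0.818 to 1.80%) and 5.19% of LCL161 cells (101 cells, 4.25 to 6.27%), a difference of 3.95 percentage points (2.86 to 5.11). B-cell-like cells numbered 27 and 92, a difference of 3.49 points (2.43 to 4.61). Mononuclear phagocyte-like cells, the macrophages and monocytes that take up debris and present antigen, were 42.1% of vehicle cells (917 cells) and 30.2% of LCL161 cells (588 cells), and neutrophil-like cells were 40.3% and 33.0%. Within the phagocytes, macrophage-like cells went from 34.3% to 21.6% while monocyte-like cells stood at 7.80% and 8.58%. Dendritic-cell-like cells were 11.6% and 12.6%, a difference whose interval held 0. Within that class the types moved in different directions. The cDC1-like cells were 3.44% and 1.64% of kept cells (-1.80 points, -2.79 to -0.809). Mature cells were 4.27% and 5.91% (1.64 points, 0.270 to 3.04). Plasmacytoid cells were 0.275% and 1.39% (1.11 points, 0.541 to 1.76), and cDC2-like cells 3.58% and 3.65%. Among T-cell-like cells, the sub-clusters named naive or central held 2 and 33 cells, regulatory 4 and 29, and CD4 15 and 20 (Cd4 seen in 12 and 19 of them). A cycling sub-cluster with Gzmk held 6 and 19 cells. Its marker score named it CD8, but its vehicle cells had 0 Cd8a and 0 Cd8b1 UMIs, and Cd4 was seen in 3 and 8 cells. Its 19 LCL161 cells held 90 Cd8a UMIs in 4 cells and 116 Cd8b1 UMIs in 6. It is therefore read as mixed and not as CD8. In the naive or central sub-cluster Cd8a was seen in 15 of the 33 LCL161 cells. In the regulatory sub-cluster Foxp3 was seen in 27 of the 29 LCL161 cells, but Cd8a was also seen in 7 and Cd8b1 in 10. NK-cell-like cells numbered 7 and 13, plasma-cell-like cells 4 and 22, and mast or basophil-like cells 9 and 21.

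These shares are of CD45-sorted barcodes with at least 500 UMIs in libraries of different depth. Under the order-of-magnitude rule for calling cells the neutrophil difference went from -7.33 to -0.693 points and the phagocyte difference from -11.8 to -20.6, and with each library clustered on its own the T-cell difference was 0.233 points, with 10 vehicle and 158 LCL161 barcodes left unnamed. Mixed-lineage barcodes, set apart from all classes, were 1.42% of vehicle and 9.04% of LCL161 barcodes, and unnamed clusters held 0.229% and 1.49%. Every mixed-lineage pair has a T-cell or B-cell member, so this share can rise with the number of lymphocytes. With mixed-lineage barcodes kept in their cluster's class, the T-cell and B-cell differences were 7.73 and 6.96 points.

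**Figure D1:**
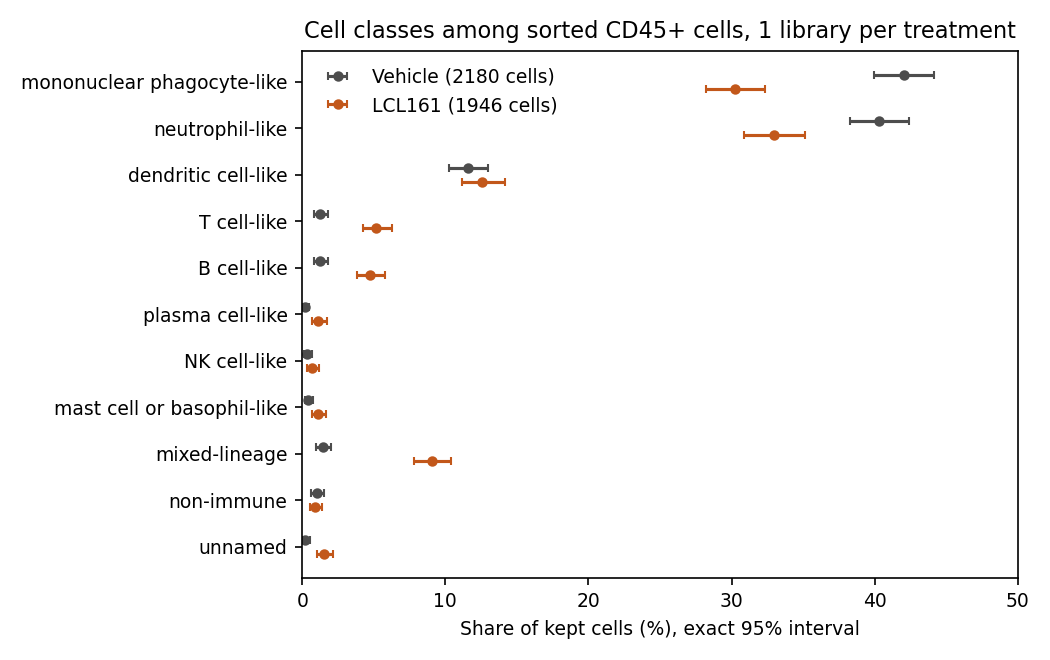
Share of kept cells (%) in each cell class for the vehicle and the LCL161 library, with exact 95% intervals that cover counting error only. T-cell-like cells stand at 1.24% and 5.19%, and mononuclear phagocyte-like cells at 42.1% and 30.2%.

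The second comparison asked how the mononuclear phagocytes differed. Chemokine and cytokine genes were lower in the LCL161 library: Ccl7, a monocyte attractant, went from 445 to 98.2 CPM (log2 ratio -2.18, interval -2.32 to -2.04), Ccl12, another CCR2 ligand, had a ratio of -1.80 (-1.95 to -1.65), Osm, an inflammatory cytokine, -1.80 (-1.99 to -1.61), and Il1a -1.53. Tnf, encoding tumour necrosis factor, was lower, at 80 and 17 UMIs (-1.79, -2.64 to -1.03). Lyz1, a lysozyme gene, was higher at 1.74 (1.60 to 1.88), as were Chil3 (0.97) and Spp1, encoding osteopontin (0.95, from 253 to 489 CPM). Retnla, an alternative activation gene, was at 678 and 1479 CPM (1.13), and Ccl17, a ligand of CCR4, at 116 and 276 CPM (1.25, 1.13 to 1.38). Among the other highest ratios were Ear2 (1.61), Ly6i (1.27), Plet1 (1.16), Unc119 (1.01), Cd24a (0.93) and Plxnd1 (0.87), and among the lowest the tissue macrophage genes Lyve1 (-2.60), Fcna (-2.40), Ms4a7 (-1.98) and Cd72 (-2.11). Genes of exocrine pancreas, Reg3b (-2.60), Cel (-2.48), Reg2 (-2.38), Ctrl (-2.35), Rnase1 (-2.34), Pnliprp1 (-2.14) and Try5 (-2.11), were also lower. For each of them 1 cell held 36.3% or more of the UMIs (68.2% for Cel, 57.1% for Ctrl and 59.5% for Pnliprp1), and without it they were, in this order, at -1.52, -0.24, -1.34, -0.62, -0.99, -0.33 and -1.07. All 7 were above 0 with the ambient profile subtracted at 10% (0.023 for Ctrl to 2.78 for Try5), and Cel and Ctrl were at 0.10 without the Ccl8 cluster described below and at 0.20 and 0.17 at Leiden resolution 2.0. For Clu (2.36), 74.4% of the UMIs lay in 1 cell, and without that cell the ratio was -0.90.

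Different clusters held the class in the 2 libraries. A cluster led by Ccl8, Cbr2, Fcna and Folr2, with the elastase gene Cela1 also among its 10 leading genes, had 333 vehicle and 72 LCL161 cells, one led by Retnla, Ear2 and Lyz1 had 39 and 95, a monocyte-like cluster led by Vcan had 170 and 167, one led by Mmp12, Cxcl9 and Ccl24 had 191 and 108, and one led by Slc7a2, Mt2, Arg1 and Spp1 had 140 and 120. The class ratios of these leading genes therefore move with the clusters, and the values within a cluster stand apart from that. Within the Ccl8, the monocyte-like, the Mmp12 and the Slc7a2 cluster in turn, Ccl7 was lower in each (-1.64, -0.70, -2.48 and -2.61), as was Ms4a7 (-0.87, -0.78, -1.55 and -0.33), and Lyz1 was higher in each (1.82, 3.68, 1.70 and 4.17). In the whole class, Lyz1 was seen in 72 of 917 vehicle and 102 of 588 LCL161 cells. Its ratios within clusters therefore rest on few cells. Retnla differed in direction among the Ccl8, monocyte-like, Mmp12 and Slc7a2 clusters (-0.13, -2.28, 0.77 and 0.50) and came to -0.048 with these clusters weighted equally. That weighting left out clusters with few cells in a library, among them the one led by Retnla, Ear2 and Lyz1 (39 vehicle cells). Ccl17 was 1.45 within the Mmp12 cluster, but was -0.22 in the class with cells kept from 300 UMIs and -0.21 with doublets kept, and Plet1 was -0.067 with cells kept from 300 UMIs.

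By gene list, the phagocytes showed lower inflammatory, complement and phagocytosis genes in the LCL161 library. The 16 measured inflammatory cytokine and activation genes had a median ratio of -0.48 (range -0.61 to -0.31), below all 10000 random lists, with 6 members lower and 1 higher beyond 1.5-fold. Complement genes, which opsonise debris, had a median of -0.51 over 10 members with 5 lower, led by C1qa (-0.89) and C1qc (-0.77), while C3 stood at 0.13. The median of 20 phagocytosis and scavenger receptor genes was -0.28, with Stab1 at -1.14 and Cd209f at -2.82 (47.2% of UMIs in 1 cell) among 4 lower members. It was at -0.20, -0.11, -0.18 and -0.37 within the Ccl8, monocyte-like, Mmp12 and Slc7a2 clusters, and at -0.15 in the class without the Ccl8 cluster. Chemokines had a median of -0.33 with 8 of 18 lower and 2 higher, Cxcl13 (1.71, 44.8% of UMIs in 1 cell) among these. Type I interferon response genes were at -0.34 over 21 members, with Oasl1 at -1.20 and Ifit3 at -0.96. Within the Ccl8, monocyte-like and Slc7a2 clusters they were at -0.88 (18 of 20 lower), -0.41 and -0.41, and within the Mmp12 cluster at 0.040 (-0.16 to 0.30). Alternative activation and tumour macrophage genes split, 3 of 18 being higher and 7 lower, with a median of -0.12 at percentile 2.47. Cholesterol and lipid handling had a median of -0.31, with the lipoprotein gene Apoe at -0.90 and the sterol sensor Nr1h3 at -1.43, but stood at -0.066 (-0.22 to 0.024) in macrophage-like cells alone and at -0.16, -0.18, -0.14 and -0.13 within the Ccl8, monocyte-like, Mmp12 and Slc7a2 clusters. MHC class II presentation genes were higher by a small amount, with a median of 0.16 over 13 members at percentile 99.5, H2-DMb2 at 0.59 and Cd86 at -0.52. Glycolysis and hypoxia genes had a median of 0.16, with Aldoa at 0.35 and Vegfa at -0.82. The list was -0.13 in monocyte-like cells alone. It was -0.060 both with the Ccl8, monocyte-like, Mmp12 and Slc7a2 clusters weighted equally and without the Ccl8 cluster.

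Beside these groups, the dissociation and immediate early stress list was also lower in the class (median -0.53 over 17 members, 7 lower, Nr4a1 -1.90 and Egr1 -1.46), and so was the acinar list (-1.69 over 8 members, 7 lower), though this list was at 0.044 at Leiden resolution 2.0, at 0.13 without the Ccl8 cluster, and at 2.55 and 3.25 with the ambient profile subtracted at 5% and 10%. Within the Ccl8, monocyte-like, Mmp12 and Slc7a2 clusters the inflammatory list was at -0.58, -0.54, -0.82 and -1.25, and the stress list at -0.44, -0.67, -0.60 and -0.83. Complement differed in direction among these clusters (-0.13, 0.35, -0.51 and -0.73). Over all alternatives the medians in the class lay between -0.73 and -0.17 for the inflammatory list, -0.62 and 0.35 for complement, -0.37 and -0.11 for phagocytosis, -0.65 and -0.25 for chemokines, and -0.62 and -0.16 for type I interferon. They lay between -0.42 and -0.079 for alternative activation, -0.52 and -0.066 for cholesterol, 0.057 and 0.24 for MHC class II, and -0.73 and -0.42 for the stress list. The stress list was also lower in the neutrophil-like, dendritic-cell-like, T-cell-like and B-cell-like cells compared below. A difference in dissociation between the libraries was not tested. The lower inflammatory list here, and the lower NF-kB list in T cells, are not set apart from such a difference.

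In the phagocytes as a class, the genes of the drug's targets and the NF-kB list had ratios near 0. Birc2 had a ratio of 0.04 (-0.28 to 0.37) and Birc3 one of 0.08 (-0.13 to 0.29), with Xiap at 0.18, Map3k14 (NIK) at 0.13, Traf2 at -0.18, Traf3 at -0.37 and Nfkb2 at -0.14. Relb, an NF-kB subunit of the alternative pathway, was lower at -0.45 (-0.78 to -0.12), and Cd40 at -0.57. The list of cIAP and TNF receptor components had a median of 0.05 over 15 members with none beyond 1.5-fold, and NF-kB targets one of 0.00053 over 19 members at percentile 70.3, with 1 higher. That list was at 0.20 (-0.092 to 0.38) in the Ccl8, -0.22 (-0.34 to -0.048) in the monocyte-like, -0.056 in the Mmp12 and 0.047 in the Slc7a2 cluster, and at -0.15 in the class with cells kept from 300 UMIs. The interferon-gamma response, the programme that T-cell interferon sets off in phagocytes, had a median of -0.02 over 19 members (-0.07 to 0.11, percentile 55.0). Its clusters differed: in the Ccl8 cluster the list was at 0.53, with Cxcl9 at 1.21 (0.97 to 1.44) and Cxcl10 between 1.08 and 1.92, both T-cell attractants, whereas in the monocyte-like, Mmp12 and Slc7a2 clusters it was at -0.05, 0.02 and -0.28. In the whole class Cxcl9 was at -0.46 and Cxcl10 at -0.21, and with these clusters alone weighted equally Cxcl9 was at 0.090 and the list at 0.20. MHC class II went from 0.33, 0.21 and 0.14 in the first 3 of these clusters to -0.78 in the Slc7a2 cluster, where H2-Aa was at -0.83. H2-Aa was at 0.14 in the class and 0.76 in the monocyte-like cluster, Arg1 at -0.14, Mrc1 at -0.39, Cd274 (PD-L1) at -0.28, and Nos2 at 1.01 on 52 and 77 UMIs. Ltb was at 0.78, but at -0.11 with cells thinned to 1000 UMIs and at -0.027 and -0.063 with the ambient profile subtracted at 5% and 10%.

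**Figure D2:**
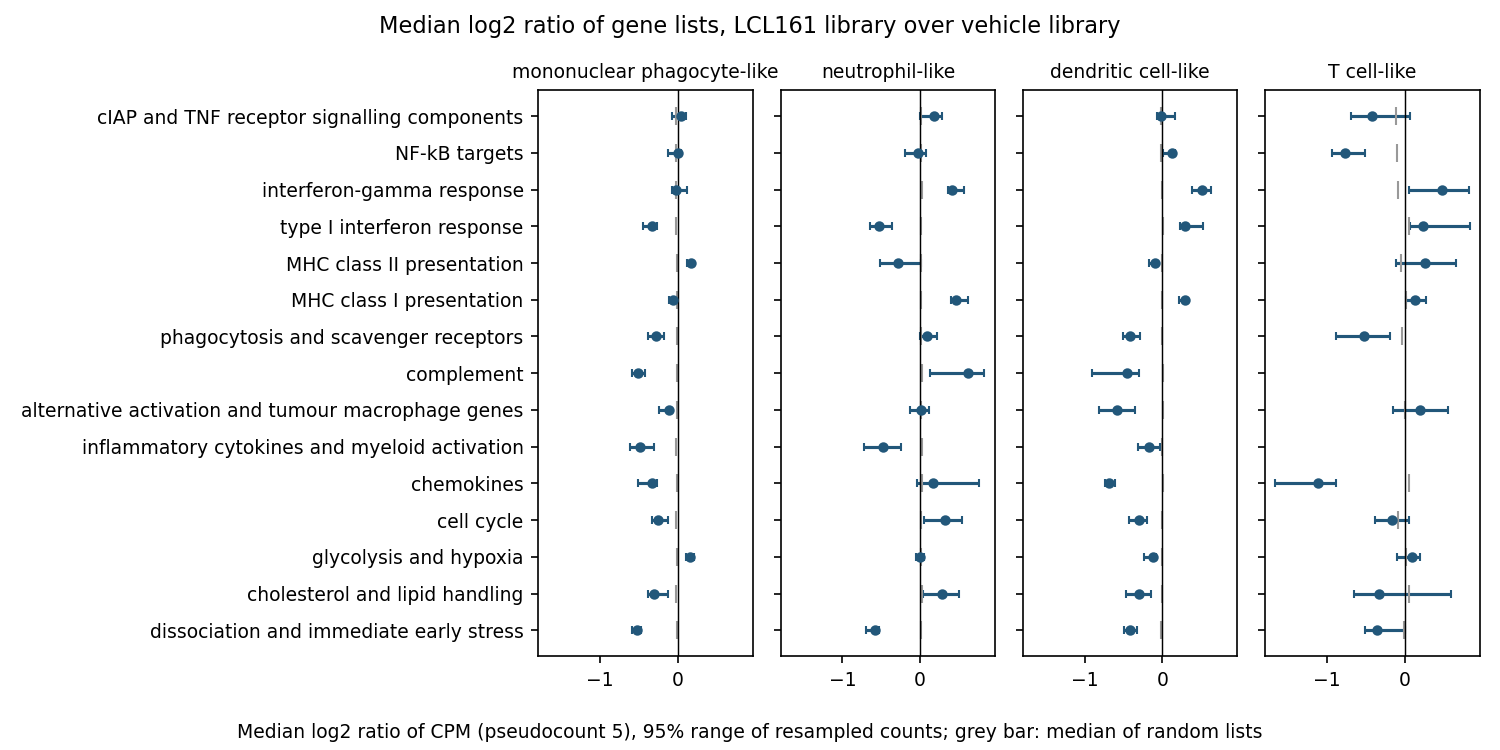
Median log2 ratio (LCL161 over vehicle) of the measured members of 15 gene lists in 4 cell classes, with 95% ranges from resampling the counts and grey bars for the medians of random lists matched on expression. In mononuclear phagocyte-like cells the inflammatory list sits at -0.48 and MHC class II at 0.16, while in T-cell-like cells the NF-kB targets sit at -0.76.

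The third comparison asked how the T cells differed. The CD8 genes and genes of naive or circulating T cells were higher in the LCL161 library: Cd8a went from 0 to 206 UMIs, 15.7-fold higher as a bound from 3 UMIs (exact lower limit of the log2 ratio 3.66), and Cd8b1, the other CD8 chain, from 1 to 335 UMIs (log2 ratio 6.26, interval 3.77 to 11.57). Klf2, which maintains naive T-cell trafficking, had a ratio of 4.54 (2.98 to 6.82), the granzyme gene Gzmk 4.31 and Klf3 3.17. Mkl1 (2.98), Arsb (2.82), Irf9 (2.73), Cd84 (2.69), the proapoptotic gene Bcl2l11 (2.58) and Hsd11b1 (2.49) were also among the highest, each on 2 to 4 vehicle UMIs, but Arsb was at -0.26 as a mean of per-cell CPM and Cd84 at -0.18 with cells thinned to 1000 UMIs. Lower were Rbpj, the transcription factor of Notch signalling (-1.97), Zeb2 (-2.21), the cytokine gene Csf1 (-2.33), and the nucleolar or repair genes Gnl3 (-2.67), Mrto4 (-2.20) and Apex1 (-2.45), with Fam213a (-2.94, and -0.48 without 1 cell that held 51.5% of its UMIs), Samd1 (-2.68) and Igfbp7 (-2.33, and -1.23 without its leading cell). The chemokine genes Ccl4 (-2.91) and Ccl3 (-2.66) rested on 1 cell for 54.4% and 48.4% of their UMIs, and were -0.11 and -0.23 without it. Gcg, the glucagon gene of pancreatic islets, was 161-fold lower as a bound from 3 UMIs (exact upper limit of the log2 ratio -7.00). Of its 110 vehicle UMIs, 95.5% lay in 1 cell.

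By list median, T-cell-like cells had lower NF-kB targets, a lower joint list of inhibitory receptor and exhaustion genes, and higher naive and memory genes in the LCL161 library. The NF-kB median was -0.76 (-0.93 to -0.51) over 16 members, below all random lists, with 12 lower and 1 higher, and Tnip1 at -1.31, Nfkb2 at -1.01 (-1.67 to -0.32) and Relb at -0.88 (-1.76 to 0.059). It was at -0.94 within the CD4, -0.93 within the cycling and -0.70 (-1.09 to 0.31) within the regulatory sub-cluster, the last 2 on 6 and 4 vehicle cells. Birc2 was lower at -1.02 (-1.73 to -0.27) and Birc3 stood at -0.66 (-1.61 to 0.38), and the cIAP and TNF receptor list was at -0.41. Inhibitory receptor and exhaustion genes had a median of -0.66 over 13 members with 8 lower, Bhlhe40 at -1.90 and Cd200 at -1.20. The receptor gene Pdcd1 (PD-1) was at -0.16 (-0.58 to 0.29), an interval that held 0, so that the lower median does not extend to it. Naive and memory genes had a median of 1.10 over 10 members with 8 higher and none lower. The interferon-gamma response was at 0.48 over 13 members (0.06 to 0.82), with Tgtp2 at 2.12 and Gbp2 at 1.75, and the type I interferon list at 0.24 (-0.31 with each library clustered on its own). T-cell cytokines and costimulation had a median of -0.01 over 11 members (-0.25 to 0.22), with Ifng at 0.34 (-0.47 to 1.24) and the lymphotoxin genes Lta at -0.55 and Ltb at -0.01. For Ifng and Lta 1 cell held 46.9% and 59.1% of the UMIs, and without it they were at -0.73 and -2.08. The cytotoxic list split, with 5 of 17 members higher and 5 lower (median -0.27, -0.46 to 0.32), Gzmb being higher at 1.14 (86 and 830 UMIs, 31.2% of them in 1 cell, without which it was at 0.55) and Gzmd at 2.19. Foxp3, the regulatory T-cell factor, was at 1.08 (0.44 to 1.79), with the regulatory list at 0.07. The stress list was at -0.36 in these cells.

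The vehicle values rest on 27 cells, most of them in the CD4 sub-cluster, whereas the naive or central, regulatory, CD4 and cycling sub-clusters each held a good part of the LCL161 cells, so that class ratios of subset genes move with the subsets. TMM scaling shifted all T-cell ratios by 0.17, and the cytokine, cytotoxic, regulatory and stress medians changed sign among the alternatives (from -0.73 to 0.29, -0.94 to 0.32, -0.45 to 0.24 and -0.76 to 0.087). The interferon-gamma median lay between 0.11, with mixed-lineage barcodes kept, and 0.68, the inhibitory receptor median between -1.14 and -0.31, and the cIAP list between -0.98 and -0.049.

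Shares of T-cell-like cells with a UMI, thinned to 1000 UMIs with 3 vehicle and 5 LCL161 cells left out (median depths 8532 and 9974.5), did not order the libraries for the effector genes. Ifng was seen in 12.5% of 24 vehicle cells (2.66 to 32.4%) and 4.17% of 96 LCL161 cells (1.15 to 10.3%), unthinned 14.8% and 16.8%, against 0 of 26 and 0 of 90 B-cell-like cells (depths 9801.5 and 10659), which allow up to 11.5% and 3.33% (3 cells; the exact upper limits are 13.2% and 4.02%). Unthinned, an Ifng UMI was seen in 0 of 917 vehicle and 0 of 588 LCL161 phagocyte-like cells, so that free RNA does not account for it. Gzmb was seen in 12.5% of cells in both libraries, unthinned 18.5% and 31.7%, against 3.85% and 0 in B-cell-like cells. The proliferation gene Mki67 was seen in 20.8% and 9.38%, unthinned 22.2% and 31.7%, against 0 and 1.11%. Lta was seen in 8.33% and 1.04%, unthinned 14.8% and 7.92%, against unthinned shares of 11.1% and 5.43% in B-cell-like cells, which also carry the gene and so give no background for it.

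In mononuclear phagocyte-like cells (53 and 44 shallow cells left out, depths 7404.5 and 9161.5), with T-cell-like cells as background, Cxcl9 was seen in 8.22% (6.47 to 10.3%) and 4.78% (3.15 to 6.92%), unthinned 14.0% and 13.1%, against 0 of 24 and 0 of 96, which allow up to 12.5% and 3.13% (exact upper limits 14.2% and 3.77%). In neutrophil-like cells, a larger background of lower depth (medians 2083 and 2671), unthinned Cxcl9 was seen in 2 of 879 and 9 of 642, below the phagocyte shares. Arg1 was seen in 39.4% and 37.9%, unthinned 56.9% and 54.6%, against 0 and 1.04%. H2-Aa was seen in 81.6% and 84.6%, unthinned 86.4% and 89.5%, against 8.33% and 6.25%. Cxcl10, at 4.05% and 3.68% (unthinned 7.42% and 7.48%), stood against 1 of 24 T-cell-like cells in the vehicle library (interval 0.105 to 21.1%) and 0 of 96, too few to fix a background level for it. Mki67, at 1.62% and 2.02% (unthinned 6.98% and 7.99%), lay below the share in T-cell-like cells, which hold a cycling sub-cluster and so give no background for it.

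Dendritic cells, which prime T cells, were compared next. Interferon-gamma response genes were higher in the LCL161 library, with a median of 0.51 over 19 members (0.38 to 0.62), above all random lists, 7 higher and 1 lower, and Iigp1, a guanosine triphosphatase induced by interferon, at 1.77. Type I interferon genes were at 0.29 with 8 of 21 higher, and MHC class I genes at 0.29, led by H2-Q7 (0.65) and H2-Q6 (0.64). Within the cDC2-like cells (78 and 71 cells) the interferon-gamma list was at 1.05 (0.80 to 1.24) with 14 of 18 higher and the type I list at 0.83, whereas in the mature cells (93 and 115), which carry Ccr7 to lymph nodes, they were at 0.01 and -0.55, and in the cDC1-like cells (75 and 32) at 0.27 and 0.46. Il1b (-1.56, -1.70 to -1.41), Cxcl9 (-1.32, and -0.67 without its leading cell), Trib1 (-1.15), Egr1 (-1.56) and Ier3 (-1.09) were the lowest ranked genes, and the stress list, which holds Egr1 and Ier3, was at -0.42. Chemokines were at -0.68 with 9 of 16 lower. Relb was higher at 0.65 (0.50 to 0.79), Birc2 at 0.38 (0.21 to 0.56), Traf2 at 0.53, Ltb at 0.90 and Nfkb2 at 0.27, with Map3k14 at -0.34 and NF-kB targets at 0.12 over 20 members. Within the mature cells Relb was at 0.34, Birc2 at 0.07 and Map3k14 at -0.69. Among the alternatives the dendritic-cell medians lay between 0.11, with cells thinned to 1000 UMIs, and 0.59 for interferon-gamma, 0.16 and 0.49 for type I interferon, and 0.24 and 0.32 for MHC class I. They lay between -1.04 and 0.00, with the ambient profile subtracted at 10%, for chemokines, -0.53 and -0.30 for the stress list, and 0.050 and 0.16 for NF-kB targets.

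The highest ranked genes Cox6a2 (3.08), Ly6d (3.07), Ccr9 (2.48) and Siglech (2.32) mark plasmacytoid cells, which numbered 6 and 27, and Cox6a2 was at -0.16 without them. Cxcl10 (3.78) had 70.4% of its UMIs in 1 cell, without which it was at 0.99. Ccr7 was seen in 31.4% (25.7 to 37.6%) and 40.9% (34.7 to 47.4%) of dendritic-cell-like cells thinned to 1000 UMIs, unthinned 36.1% and 47.3%, against 12.5% and 2.08% of T-cell-like cells, some of which carry the gene too, with 7 and 3 shallow cells left out and depths of 13259 and 12134. Il12b, the interleukin-12 subunit, was lower at -0.88 (-0.04 without its leading cell), and its thinned shares of 1.63% and 0.826% (unthinned 11.1% and 6.12%) stood against 0 of 24 and 0 of 96 T-cell-like cells and, unthinned, 3 of 917 and 0 of 588 phagocyte-like cells, so that the unthinned shares are above background.

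Neutrophils, phagocytes of acute inflammation, also carried more interferon-gamma response and MHC class I RNA in the LCL161 library. H2-Q6 went from 77 to 559 UMIs (2.93, 2.58 to 3.29) and was seen in 50 and 220 cells, and H2-Q7, a second non-classical class I gene, had a ratio of 2.76 (2.46 to 3.07). The MHC class I list was at 0.46 over 18 members (0.39 to 0.62) with 8 higher, and the interferon-gamma list at 0.41 over 17 members with 7 higher, including Gbp4 at 2.37. Saa3, an acute phase gene, was at 3.14, Chil3 at 4.03, Arg1 at 2.23 and Nos2 at 1.92. Barcodes with both neutrophil and phagocyte markers were not set apart from this class. Type I interferon genes were lower at -0.52 with 8 of 19 lower and Rsad2 at -1.73, and inflammatory genes at -0.48 with Osm at -1.52, Ptgs2 at -1.39 and Tnf at -1.07. The heat shock genes Hspa1b (-3.83) and Hspa1a (-2.72), Rcan1 (-2.61) and Nr4a1 (-2.12) were the lowest, and the stress list stood at -0.58 with 8 of 17 lower and the acinar list at -1.79. Camp, a granule gene of immature neutrophils, was 484-fold higher as a bound from 3 UMIs (exact lower limit of the log2 ratio 8.62). It lay in 3 cells, and Ngp (8.89) in 5 LCL161 cells. A neutrophil cluster led by Rsad2 and Ifit genes held 54 and 24 cells, and reads of near-identical copies, such as H2-Q6 and H2-Q7 or Hspa1a and Hspa1b, are not told apart with certainty, so that each pair is uncertain gene by gene. Among the alternatives the neutrophil medians lay between 0.30 and 0.62 for MHC class I, 0.26 and 0.75 for interferon-gamma, -0.62 and -0.14 (under the order-of-magnitude rule) for type I interferon, -0.89 and -0.17 (at a pseudocount of 50 CPM) for the inflammatory list, -0.66 and -0.51 for the stress list, and -2.95 and 0.00 for the acinar list.

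**Figure D3:**
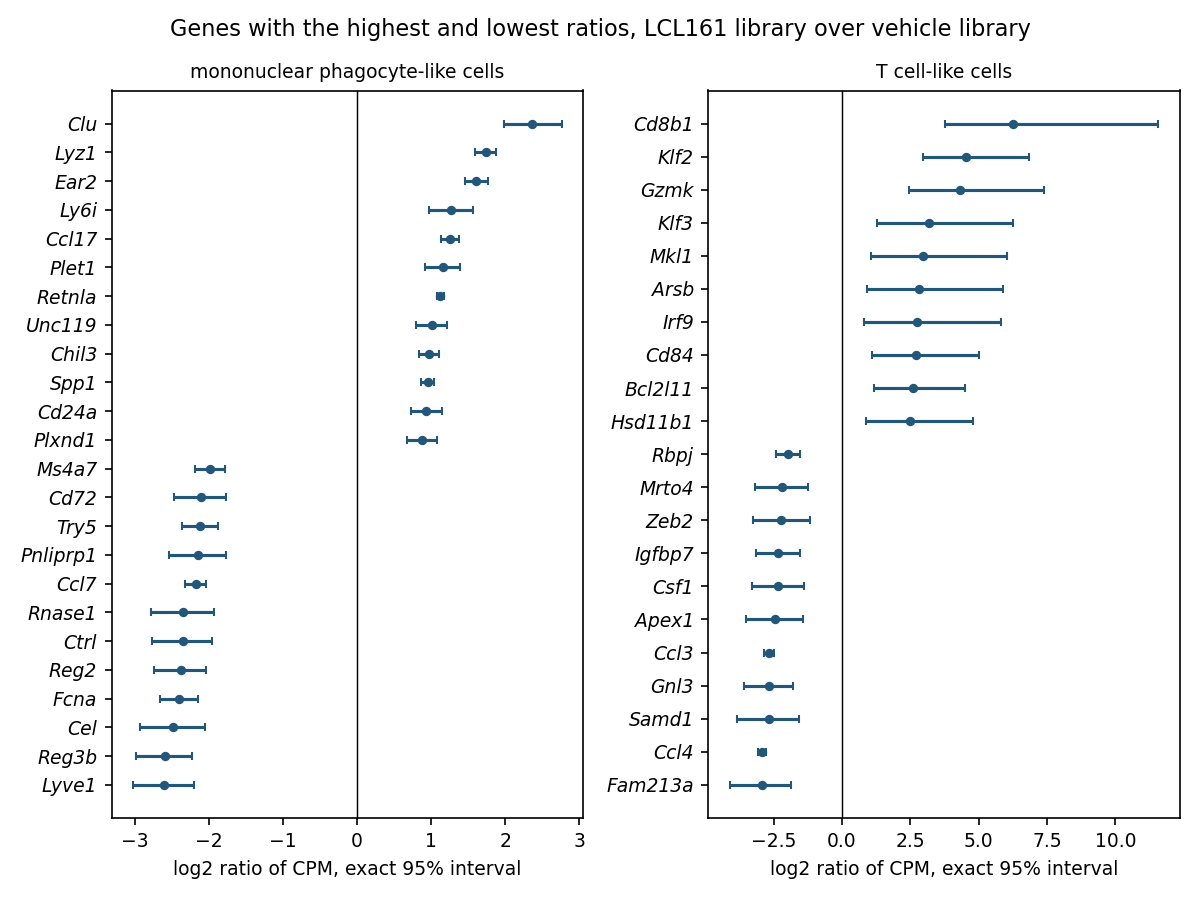
Log2 ratio (LCL161 over vehicle) of CPM for the ranked genes reported in mononuclear phagocyte-like and T-cell-like cells, with exact 95% intervals that cover counting error only; Cd8a and Gcg, which are bounds, are not drawn. In the phagocytes Lyz1 sits at 1.74 and Ccl7 at -2.18, and in the T cells Cd8b1 sits at 6.26 and Rbpj at -1.97.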

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

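The 2 tests in this part, on free acinar RNA and on a few barcodes, were chosen only after the result was seen. Non-immune clusters, which a CD45 sort should remove, held 1.01% of vehicle cells (22 cells, 0.633 to 1.52%) and 0.874% of LCL161 cells (17 cells, 0.510 to 1.40%), and enter the comparisons only through the total of kept cells that shares are taken of. RNA of the 8 acinar genes, all made by the exocrine pancreas around a tumour and all also used here as acinar markers, made up 323 per 10000 UMIs in the nearly empty barcodes (1 to 50 UMIs) of the vehicle library and 5.82 in those of the LCL161 library.

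The same RNA stood out in the vehicle mononuclear phagocytes, with Ctrb1 at 498 and 105 CPM and Prss2 at 244 and 48.3 CPM in the vehicle and LCL161 library. Clusters were formed again after 42 exocrine genes were removed from the counts. Then 43.5% of vehicle cells of the Ccl8, Cbr2 and Fcna cluster held an acinar UMI, against 31.6% of neutrophil-like cells, 11.9 points more (5.56 to 18.3), and 31.4% of the other phagocytes. This argues against free acinar RNA as the whole cause only if a droplet takes up a like amount whatever its cell. The shares were not thinned, so depth was not held equal. Vehicle cells of the Ccl8 cluster as first formed had a median of 5307 UMIs, and neutrophil-like cells one of 2083. A few barcodes may account for most of the molecules: 10 of 917 vehicle phagocytes held 91.3% of the 10246 acinar UMIs, as barcodes that also hold an acinar cell would. Attached acinar cells and engulfed acinar material were not tested against each other, and an effect of treatment on acinar tissue stays open, as untested. The class ratios of Reg3b, Reg2, Cel, Ctrl, Try5, Rnase1 and Pnliprp1 carry this limit.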

How the results depend on the processing

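With 1 library per group, counting error is the only spread that could be set beside an alternative, and no alternative here stands for a replicate. No paired analysis was possible because each group has 1 library. Share differences stayed within their counting intervals in 109 of the comparisons with an alternative and left them in 20, with no change of sign for those whose interval excluded 0. List medians stayed within theirs in 1912, left them in 314 and, from a range that excluded 0, changed sign in 39; named genes did so in 3086, 370 and 35; shares of cells with a UMI stayed within theirs in 19 and left them in 3. Counting also values whose range held 0, 169 list medians, 107 gene ratios, 6 differences in shares of cells with a UMI and 1 class share difference changed sign. The T-cell difference lay between 0.233 and 10.8 points. The lowest of these was near 0, on 33 vehicle and 34 LCL161 T cells with each library clustered on its own, and has no interval here. The phagocyte difference lay between -20.6 and -7.87 and the neutrophil difference between -11.4 and -0.693, always below 0. In T cells the NF-kB median lay between -0.95 and -0.46 and the naive and memory median between 0.72 and 1.93, and in phagocytes the inflammatory median between -0.73 and -0.17. With each library clustered on its own, 158 LCL161 barcodes stayed unnamed and 34 were named T cells, against 101 when clustered together. The order-of-magnitude rule has minimums of 2807 and 3287 UMIs, above the median neutrophil (2083 and 2671), and by construction left 219 and 222 neutrophils. The ambient profile of the vehicle library is rich in acinar RNA, so that subtracting it removes acinar counts from that library by construction. For all other values below the cause was not tested. Depth limits the lymphocyte ratios, with 257734 vehicle UMIs in T cells, 244930 in B cells and 64629 in NK cells, against 6965212 in the phagocytes. Values are log2 ratios, or percentage points for shares.

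With cells kept from 300 UMIs, the NF-kB, MHC class II and cell cycle medians in phagocytes were -0.15, 0.088 and 0.15, and Ccl17 and Plet1 in phagocytes were -0.22 and -0.067. With cells kept from 1000 UMIs, the MHC class II and cell cycle medians in phagocytes were 0.079 and 0.15. Under the order-of-magnitude rule for calling cells, the share differences of phagocytes, T cells and neutrophils were -20.6, 5.30 and -0.693 points, and the T-cell cytokine median in T cells was 0.29. At a mitochondrial share under 5%, the inhibitory receptor median in phagocytes was 0.0052, and Clu in phagocytes was -0.86. There the cytotoxic and T-cell cytokine medians in T cells were 0.32 and 0.26. With doublets kept, Ccl17 in phagocytes was -0.21. At Leiden resolution 0.5, the MHC class II and cell cycle medians in phagocytes were 0.10 and 0.14. At Leiden resolution 2.0, the share difference of phagocytes was -7.87 points, and the MHC class II and acinar medians in phagocytes were 0.24 and 0.044. There Clu, Cel and Ctrl in phagocytes were -0.21, 0.20 and 0.17. With each library clustered on its own, the share differences of T cells and neutrophils were 0.233 and -11.4 points, and the red cell median in phagocytes was -1.05. There the type I interferon, cytotoxic, T-cell cytokine and inhibitory receptor medians in T cells were -0.31, -0.94, -0.73 and -1.14, and the cell cycle median in dendritic cells was 0.18. With classes set per cell by highest mean marker level, the share differences of T cells and B cells were 7.50 and 5.99 points, and the MHC class II, alternative activation, inhibitory receptor and naive medians in phagocytes were 0.093, -0.25, 0.24 and 0.11. There Clu and Cel in phagocytes were -0.31 and 0.11, and the cytotoxic median in neutrophils was 0.52. There H2-Aa in neutrophils was 0.32. As a share of immune classes only, the share difference of neutrophils was -4.18 points. With TMM scaling, the MHC class II median in phagocytes was 0.18. Centred on the median of all genes, the MHC class II median in phagocytes was 0.19. As a mean of per-cell CPM, the MHC class II median in phagocytes was 0.18, and the T-cell cytokine median in T cells was -0.55. There Arsb in T cells was -0.26. With cells thinned to 1000 UMIs, the NF-kB, interferon-gamma, alternative activation, inflammatory, T-cell cytokine and naive medians in phagocytes were -0.21, 0.19, -0.079, -0.73, -0.18 and 0.067, and Ltb in phagocytes was -0.11. There the cytotoxic, T-cell cytokine and inhibitory receptor medians in T cells were -0.54, -0.41 and -0.99, and Cd84 in T cells was -0.18. There the cholesterol median in dendritic cells was 0.32. With the ambient profile subtracted at 5%, the T-cell cytokine and acinar medians in phagocytes were -0.014 and 2.55, and Reg3b, Reg2, Try5, Rnase1, Pnliprp1 and Ltb in phagocytes were 1.79, 1.92, 2.84, 1.59, 1.87 and -0.027. There the acinar median in dendritic cells was 0.89. Subtracting it at 10%, the T-cell cytokine, regulatory T and acinar medians in phagocytes were -0.052, -0.021 and 3.25, and Reg3b, Reg2, Cel, Ctrl, Try5, Rnase1, Pnliprp1 and Ltb in phagocytes were 1.73, 1.80, 1.59, 0.023, 2.78, 1.54, 1.89 and -0.063. There the acinar median in dendritic cells was 0.26. At a pseudocount of 50 CPM, the MHC class II, phagocytosis and inflammatory medians in phagocytes were 0.10, -0.14 and -0.17. Over members with 1 or more UMIs, the inhibitory receptor median in phagocytes was 0.040, and the cytotoxic median in neutrophils was 0.0090. Over members with 100 or more UMIs, the cytotoxic median in T cells was 0.32. In macrophage-like clusters alone, the interferon-gamma and MHC class II medians in phagocytes were -0.19 and 0.057. In monocyte-like clusters alone, the NF-kB, MHC class II, MHC class I, phagocytosis, complement, alternative activation, T-cell cytokine, regulatory T, cell cycle and glycolysis medians in phagocytes were -0.22, 0.21, 0.085, -0.11, 0.35, -0.42, -0.025, -0.41, 0.13 and -0.13. Without cycling clusters, the T-cell cytokine and inhibitory receptor medians in T cells were -0.33 and -1.07.

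The following were chosen only after the data were seen, as were a tie at 0.95 and a naming score without leading genes, under which no value left its interval, and T cells without the naive or central sub-cluster. The first rule for leading genes, the first reference for folds and the naming without the comparison of markers between classes were not run. With mixed-lineage barcodes kept in their cluster's class, the share differences of T cells and B cells were 7.73 and 6.96 points, and the naive median in phagocytes was 0.13. There the MHC class I and inhibitory receptor medians in T cells were -0.049 and -0.31. Counting marker-positive barcodes of any class, the share differences of T cells and B cells were 10.8 and 7.86 points. With sub-clusters at resolution 1.0, the MHC class II and cell cycle medians in phagocytes were 0.10 and 0.14. With no minimum cluster size, the MHC class II and cell cycle medians in phagocytes were 0.10 and 0.15. Without the cell with most UMIs of the gene, Clu in phagocytes was -0.90. The equal weighting of phagocyte clusters took the Ccl8, monocyte-like, Mmp12 and Slc7a2 clusters only. With it, the interferon-gamma, MHC class I, alternative activation, naive and glycolysis medians in phagocytes were 0.20, 0.0028, -0.086, 0.060 and -0.060. There Retnla and Cxcl9 in phagocytes were -0.048 and 0.090. Without the Ccl8, Cbr2 and Fcna cluster, the NF-kB, interferon-gamma, MHC class II, MHC class I, phagocytosis, alternative activation, glycolysis and acinar medians in phagocytes were -0.19, 0.11, 0.20, 0.026, -0.15, -0.27, -0.060 and 0.13, and Clu, Cel and Ctrl in phagocytes were -0.28, 0.10 and 0.10. Without plasmacytoid clusters, Cox6a2 and H2-Aa in dendritic cells were -0.16 and 0.0017.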

Other observations

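In the tests weighed below, those of chance pairing, of depth, of lymph node tissue and of treatment were chosen only after the result was seen. B-cell-like cells, 27 and 92 in the vehicle and LCL161 library, had higher type I interferon response genes (median 1.03, 0.42 to 2.32, over 7 members, 5 higher) and MHC class I genes (0.37, 0.24 to 0.51, over 18 members), including H2-Q7 at 0.98 (0.46 to 1.54). Isg15 (2.76) had 55.2% of its UMIs in 1 cell, and the lower inflammatory list (-1.42 over 7 members) included Cxcl2, seen in 2 cells of each library. The stress list stood at -0.31 in these cells, and Hbb-bs was 1037-fold higher as a bound from 3 UMIs, all of its 12147 UMIs lying in 5 LCL161 cells. NK-cell-like cells, 7 and 13, had a cytotoxic effector median of 0.53 over 15 members (0.25 to 0.75). Unnamed sub-clusters, singled out after their values were seen, included one led by the progenitor granule genes Elane, Mpo and Prtn3 (3 and 10 cells) and one with gamma-delta T cell and innate lymphoid markers (2 and 9 cells).

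Of the lists not given above, with values under alternatives that changed the sign in brackets, in mononuclear phagocytes MHC class I was at -0.06 over 18 members (0.0028 to 0.085 in 3 alternatives), cell cycle at -0.26 over 26 (0.13 to 0.15 in 6) with Top2a at -0.96, cytotoxic effector at -0.05 over 6 (0.013 to 0.83 in 13), T-cell cytokines and costimulation at 0.34 over 8 (-0.18 to -0.014 in 4), inhibitory receptors at -0.40 over 6 (0.0052 to 0.24 in 3), naive and memory T cell at -0.18 over 8 (0.060 to 0.13 in 4), regulatory T cell at 0.27 over 6 (-0.41 and -0.021 in 2) and ductal or tumour RNA at -0.18 over 4. The red cell list was at 2.69 over 4 (-1.05 with each library clustered on its own), with 99.4% of Hbb-bs UMIs in 1 cell, and of the sex-linked list only Xist was measured, at -0.01. In neutrophils complement was at 0.62 over 7 members (0.00 with the ambient profile subtracted at 10%) with C3 at 0.92, and NF-kB targets at -0.03 (0.0022 and 0.031 in 2). In dendritic cells phagocytosis genes were at -0.41, alternative activation genes at -0.59 and cell cycle genes at -0.31 (0.18 with each library clustered on its own).

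T-marker-positive barcodes that also carried phagocyte markers numbered 22 of 56 in the vehicle and 96 of 260 in the LCL161 library, and those with B-cell markers 3 of 56 (5.36%, 1.12 to 14.9%) and 54 of 260 (20.8%, 16.0 to 26.2%), while B-marker-positive barcodes with phagocyte markers numbered 5 of 37 and 41 of 186; all were set apart from the classes above. Chance pairing of cells in droplets was weighed on barcodes with T-cell markers and phagocyte or neutrophil markers. Neutrophil markers made up 11.9% (6.51 to 19.5%) of such LCL161 pairs where pairing at random would give 45.9%, and 0 of 22 vehicle pairs (exact upper limit 15.4%). Both upper limits were also below each library's random share scaled for how often summed barcodes pass the marker rule. This argues against chance pairing only if free phagocyte RNA adds few phagocyte markers to T-cell barcodes, which was not tested. Free T-cell RNA is argued against in the LCL161 library: thinned to 1000 UMIs, 5.002 points more phagocyte than neutrophil barcodes of the LCL161 library (2.98 to 7.13) held a pair of T-cell markers. T cells attached to phagocytes, or taken up by them, may be the source, as a hypothesis that no value here tests. Whether treatment changed their frequency stays open, the share of T-marker-positive barcodes with phagocyte markers differing by -2.36 points (-17.5 to 11.8) between single libraries. As a share of phagocyte-marker-positive barcodes, those with T-cell markers were 2.29% (1.44 to 3.45%) in the vehicle and 13.1% (10.8 to 15.8%) in the LCL161 library. T-marker-positive barcodes as such were also more numerous in the LCL161 library.

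T-cell-like and B-cell-like cells together made up 7.44 points more (5.95 to 8.98) of the LCL161 library. The greater depth of this library is argued against for the T-cell-like cells. Its barcodes were thinned until the median of those kept was 3485 to 3497 UMIs (105 or 106 then fell below the minimums). Both libraries were then clustered and named again. The T-cell difference in 5 such draws was at least 4.09 points (3.01 to 5.25), and in 5 draws thinned by the ratio of medians (3827 to 3840 UMIs left) at least 4.11. The prediction was on T-cell-like cells alone, so depth stays open for the B-cell-like cells. Lymph node tissue in the LCL161 sample may account for the T-cell-like and B-cell-like cells, as no marker here separates node from tumour and a node holds T-cell subsets and B cells alike. Treatment, node tissue and any other difference between these 2 libraries cannot be told apart, with 1 library each.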
